A study of Bos taurus with 3 samples.

How the data were processed

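Gene expression was measured on 3 two-colour Agilent bovine arrays, 1 per animal. Per the labels, the cattle were infected with bovine leukemia virus and had persistent lymphocytosis, and IgMhigh and IgMlow B cells were obtained with a cell sorter after overnight culture of mononuclear cells in RPMI medium. Gates other than IgM are not given in the sources used here. Total RNA was labelled with a low-input kit, red (Cy5) for IgMhigh and green (Cy3) for IgMlow cells on every array, per the labels' protocols. With no swap of dyes, a dye bias of a probe cannot be told apart from a difference between the fractions.

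The deposited scanner files hold spot and background intensity in both channels, with no normalization. They also hold intensity after background subtraction, detrending and linear and LOWESS dye normalization, and a log10 ratio of red over green made from it, per the file headers. The headers name Agilent Feature Extraction 10.7.3.1, whereas the submitters' processing notes name version 9.5.3, and the difference was not resolved. The authors' deposited series table holds log2 ratios. Set against each scanner file, they matched log2 of red over green processed intensity (slope at least 0.999, Pearson r at least 0.999 across probes), so direction and scale are known. Values were present only where both channels were well above background (100% of values on each array). The column medians were 0.04, 0.04 and 0.01, and no further centring was found. The 3 arrays lay on 1 slide and were scanned on 1 day per the file headers, so no slide or scan batch separates them.

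Mean spot intensity was corrected with normexp (offset 50) and normalized by loess within each array in R 4.3.3 with limma 3.58.1 (and the package data.table, version 1.17.8). Control spots had weight 0 in loess and were then removed, outlier spots (8, 5 and 8 per array) were set to missing, and spots of a probe were averaged. The offset shrinks ratios of dim probes towards 0. Of 43653 probes, 30947 (70.9%) were well above background in the same channel on at least 2 arrays and were tested. Each gene was represented by its probe with the highest mean intensity, giving 18326 genes, of which 12597 had a symbol and 5729 were single probes without one. Names came from RefSeq accessions for 27551 probes (table of assembly ARS-UCD2.0, used for names only), from a current symbol for 5635, from an older symbol for 218 and from the array's own name for 615, and 9630 had none. Some names were chosen after seeing the files: 4 immunoglobulin probes were named by their description, and old names shared with probes of a known accession were merged, which joined the probes of RIGI. Probe coordinates are those of the array files, on UMD 3.1.

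A single mean ratio over the 3 animals was fitted with lmFit and eBayes (prior degrees of freedom 3.21), two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The pairing comes from the labels: both fractions on an array came from the same animal. Ratios correlated between animals across genes (Pearson r from 0.61 to 0.65 over 18326 genes, which are not independent replicates). A dye bias shared by the arrays would raise these correlations too. Gene lists, 37 in number, were tested with camera (preset correlation 0.01, and an estimated one) and fry, adjusted over the lists. With the preset correlation 13 lists were called, 4 higher and 9 lower. With an estimated correlation 0 were called (smallest adjusted p = 0.56). From 3 arrays that correlation is estimated with very few residual degrees of freedom, and how often this variant detects a real shift was not assessed. A missing call there does not show that a shift is absent. By fry, which asks whether the genes of a list move one way on balance, 0 were called (smallest adjusted p = 0.072), and 32 when either direction counted. Lists, the tests of genes and lists, alternatives and the naming rule were fixed before the data were examined, and several tests of explanations were chosen later, as stated with them. Named were the 10 largest and 10 smallest ratios among genes past the threshold that had one sign in all animals, were well above background in a channel on all 3 arrays and had a symbol that is not a LOC number, then up to 4 members with the smallest p per list described, and 24 genes chosen beforehand. Some genes that this rule takes are not reported here.

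In simulated data each gene's variance was drawn from the prior that limma fitted to the real data, and noise was independent between genes. There limma called 45 of 50 genes changed 1.41-fold and all 50 changed 2-fold, 4-fold or 8-fold, with 7 false calls among 18126 unchanged genes. It called 0 of 36 unshifted lists. No correlation between genes and no dye bias was simulated, so these counts do not cover either. Each simulated change also had the same underlying size in all 3 animals. Of 120 genes in the real data at least 2-fold different with one sign in all animals, 49 passed. The simulated shares thus do not carry over to changes that vary between animals. Spike-in RNA of known ratio gave observed over expected slopes of 0.88, 0.87 and 0.87 per the file headers, so ratios are somewhat compressed. Alternatives covered background correction, normalization within and between arrays, the source of values, the filter on dim probes, the probe per gene, the variance model, array weights, the pairing, the threshold and leaving out each animal.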

Results

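Transcripts of IgMhigh and IgMlow B cells were compared in blood from 3 cattle infected with bovine leukemia virus, a deltaretrovirus that persists as a provirus in B cells. All 3 animals, numbered 651, 827 and 384, had persistent lymphocytosis, a lasting expansion of circulating B cells. Mononuclear cells were kept overnight in culture and then sorted by the amount of IgM. Each animal gave 1 two-colour array on which its IgMhigh RNA was red and its IgMlow RNA was green, so that each ratio was taken within 1 animal. Dyes were never swapped, and a difference between dyes is therefore part of every ratio. The median background-uncorrected signal per array was 72.9, 65.3 and 73.1 in green and 109, 109 and 124 in red, in the order of animals above. Between 65.4% and 71.3% of probes were well above background per channel and array, no spot was saturated, and the small number of arrays limits the precision. All ratios below are log2 of IgMhigh over IgMlow, given as mean with SD over n = 3 animals, with adjusted p-values from limma.

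The marker used for sorting came first, as a check of the labels. IGHM, which encodes the constant part of the IgM heavy chain, had a ratio of 0.05 ± 0.13 (SD, n = 3; limma adjusted p = 0.60), and its other probe gave 0.06. Its probe lay on chromosome 8 from 73087917 to 73088107 in assembly UMD 3.1. The IGHM transcript thus differed by less than the spread between animals, and it neither bears out nor contradicts a sort made on IgM protein. IGHD, the heavy chain of the IgD co-expressed with IgM on naive B cells, had a ratio of 0.41 ± 0.15 and missed the threshold (limma adjusted p = 0.051). IGHG1, the constant part of an IgG heavy chain, stood at 0.22 ± 0.05 (limma adjusted p = 0.066), and IGKC, the kappa light chain constant gene, at 0.17 ± 0.10 (limma adjusted p = 0.14). JCHAIN, which joins IgM and IgA into polymers, had probes of opposite sign, at -0.26 and 0.16. Of the 7 immunoglobulin genes tested, 0 passed over all genes and 2, both higher, passed when adjusted over the list alone. As a list they were not called (median 0.07, camera adjusted p = 0.16), but were with the mean of a gene's probes (0.17, camera adjusted p = 0.012) and without animal 827 (0.15, camera adjusted p = 0.02). Without loess normalization, when each array was only centred on its median, the IGHM ratio was 0.74. On that scale the median was also 0.74 for B cell identity genes and 1.11 for ribosomal protein genes, so the value is not particular to IGHM.

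Among genes with a symbol, the largest increases in IgMhigh cells stayed below 2-fold after loess. With median centring in place of loess the genes named in this paragraph had log2 ratios from 1.03 (PLD4) to 1.69 (ITPR1). In Agilent's processed signals their ratios were 0.51 (RPS18) to 0.93 (TBXA2R), and none passed the threshold. None passed without animal 651, without animal 827 or without the pairing either. IL32, a proinflammatory cytokine, rose 1.83-fold (0.87 ± 0.12, SD, n = 3; limma adjusted p = 0.017), with its probe on chromosome 25 from 2496959 to 2497018 in UMD 3.1. TBXA2R, the thromboxane receptor, rose 1.68-fold (0.75 ± 0.30), and ADORA2B, an adenosine receptor, rose 1.64-fold (0.72 ± 0.23). RIGI, a cytosolic sensor of viral RNA, rose 1.63-fold with little spread between animals (0.70 ± 0.03, SD, n = 3; limma adjusted p = 0.016). The endocytic genes DNM1, a dynamin that pinches off vesicles, and PACSIN1, a dynamin-binding protein, reached 0.73 ± 0.13 and 0.70 ± 0.14. NAPSA, an aspartic protease, stood at 0.67 ± 0.06, PLD4, an endolysosomal exonuclease, at 0.66 ± 0.24 and RPS18, a protein of the small ribosomal subunit, at 0.67 ± 0.03. ITPR1, a calcium channel of the endoplasmic reticulum, stood at 0.73 ± 0.12 on its brightest probe, but its 7 probes ranged from -0.13 to 0.73, and the 4 probes of DNM1 from -0.08 to 0.73. Probes ranged from 0.07 to 0.70 for RIGI, from 0.24 to 0.75 for TBXA2R, from 0.31 to 0.66 for PLD4 and from 0.19 to 0.67 for RPS18. With the mean of a gene's probes RIGI stood at 0.31 and RPS18 at 0.47, while TBXA2R (0.42), ITPR1 (0.26), DNM1 (0.25) and PLD4 (0.54) missed the threshold.

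The lowest ratios past the test were those of the chemokine genes CCL2 and CXCL8. CCL2, which attracts monocytes, fell 17.1-fold in IgMhigh relative to IgMlow cells (-4.10 ± 1.67, SD, n = 3; limma adjusted p = 0.047), with its probe on chromosome 19 from 16233039 to 16233098 in UMD 3.1. CXCL8, which attracts neutrophils, fell 12.9-fold (-3.69 ± 1.46; limma adjusted p = 0.045, n = 3), with its probe on chromosome 6 from 90563357 to 90563416. Both were less unequal in animal 384, at -2.29 and -2.04, than in animals 651 (-5.56 and -4.83) and 827 (-4.44 and -4.20). The median of the monocyte and macrophage markers was -0.19 in animal 384, -1.20 in animal 651 and -0.50 in animal 827. Ratios of all tested genes also spread least in animal 384 (SD over genes 0.17, against 0.30 in animal 651 and 0.25 in animal 827). T cell markers also had their smallest median in size in animal 384 (-0.22), but animal 651 (-0.56) did not exceed animal 827 (-0.63). Medians of B cell identity genes were 0.26, 0.15 and 0.26 in animals 651, 827 and 384. Small ratios in animal 384 were thus not particular to chemokines or monocyte markers, but the full order was not shared by all sets. TRD@, the T cell receptor delta chain, fell 7.40-fold (-2.89 ± 0.36), and LCK, the kinase of T cell receptor signalling, fell 2.96-fold (-1.57 ± 0.38). GCH1, the first enzyme of tetrahydrobiopterin synthesis, fell 5.39-fold (-2.43 ± 0.27), KCTD12, a subunit of GABA-B receptors, 3.66-fold (-1.87 ± 0.28), PRPS2, an enzyme of nucleotide synthesis, 3.17-fold (-1.66 ± 0.25) and ARC, an activity-regulated immediate early gene, 2.96-fold (-1.56 ± 0.17). The core histone genes H2BC21 and H2B fell by 1.63 and by 1.54 on the log2 scale, with SDs of 0.51 and 0.50. Other probes of some of these genes showed far smaller differences, down to -0.19 for TRD@, -0.20 for GCH1, -0.05 for PRPS2, -0.01 for H2BC21, -0.12 for LCK and -0.21 for H2B. With the mean of a gene's probes LCK stood at -0.98, and CCL2 (-3.30) and CXCL8 (-3.60) missed the threshold. Larger differences came from Agilent's processed signals, at -3.17 for LCK, -3.10 for KCTD12 and -3.59 for ARC, where LCK missed the threshold.

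**Figure D1:**
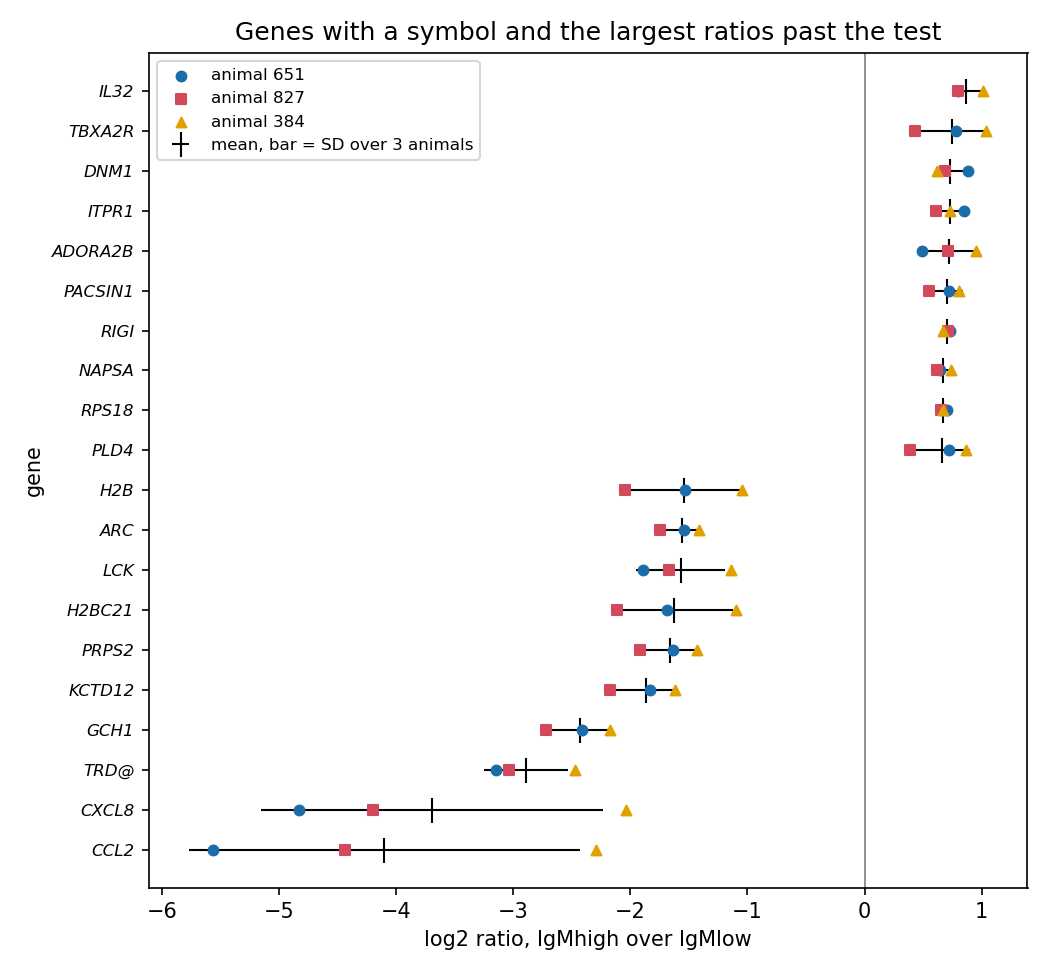
Log2 ratio of IgMhigh over IgMlow for the 20 genes with the largest increases and decreases among those past the test that had a gene symbol other than a LOC number, with 1 symbol per animal and the mean with SD over 3 animals. These increases lie below 1 on average, from 0.66 for PLD4 to 0.87 for IL32, while these decreases reach -4.10 for CCL2.

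Over the 18326 genes tested, 475 (2.59%) differed between the fractions in limma, 262 higher and 213 lower in IgMhigh cells. The increases were small, with a median of 0.38, and the decreases had a median of -0.49. Only 1 of the increases but 48 of the decreases were at least 2-fold. Of these 48, 23 were replication-dependent histone genes or probes, many of them probes without a symbol that were each counted as a gene. The single 2-fold increase, 2.15-fold, was a probe with no gene symbol, named here after its value was seen. Regardless of the test, 120 genes were at least 2-fold different with one sign in all 3 animals, 1 higher and 119 lower, and 49 of these passed. One sign in all 3 animals was found for 51.4% of all genes, where independent signs would give 25%. With the same dyes on every array, a dye bias of a probe would also give one sign. The excess therefore cannot be read as a difference between the fractions. The number of genes past the threshold fell whenever an animal was left out, and each of these fits had fewer samples. In limma 0 passed without animal 651 (3575 at an unadjusted p under 0.05), 9 without animal 827 and 224 without animal 384. A loss of power was not separated from a dependence on single animals. Without the pairing of both fractions of an animal 1 gene passed, and with median centring in place of loess 12129 passed, 83.5% of them higher against 55.2% after loess. Of 56 named genes past the threshold, 6 stayed past it in Agilent's processed signals, 30 with the mean of a gene's probes and 45 with median centring, and 10 of 53 did in the series table. In the processed signals 12 of the 56 ratios, that of TRD@ among them, were over 1.5 times as large. With the mean of a gene's probes 17 were over 1.5 times smaller. With median centring 26 were over 1.5 times as large, 9 were over 1.5 times smaller and 4 changed sign. Without animal 651, 827 or 384 the number that stayed past the threshold was 0, 4 or 32.

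**Figure D2:**
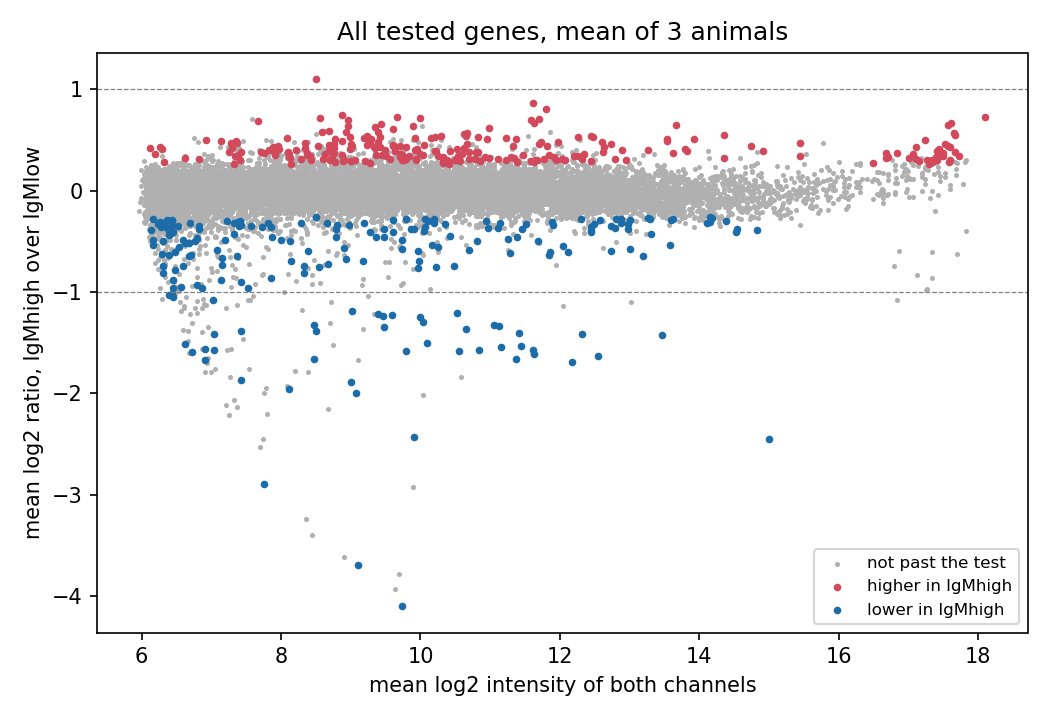
Mean log2 ratio of IgMhigh over IgMlow against mean log2 intensity of both channels for the 18326 genes tested, with dashed lines at 2-fold. The 262 genes past the test and higher in IgMhigh cells lie close to 0, the 213 lower ones reach -4.10, and the brightest genes lie mostly above 0.

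Markers of B cells were on the whole higher in IgMhigh cells. Of 22 tested genes of B cell identity, 8 rose and 0 fell (14 and 0 adjusted over the list alone), with a median of 0.21. The median was 0.74 with median centring in place of loess. BANK1, a scaffold of B cell receptor signalling, rose by 0.53 ± 0.03, CD180, a Toll-like receptor homologue, by 0.51 ± 0.04, BCL11A, a lymphoid transcription factor, by 0.54 ± 0.08, and CR2, the complement receptor that lowers the threshold of B cell activation, by 0.43 ± 0.07. MS4A1, which encodes CD20, and CD79A, a signalling chain of the B cell receptor, rose by 0.38 ± 0.07 and 0.48 ± 0.17, whereas CD79B, the partner chain of CD79A, stood at -0.01 ± 0.14 (limma adjusted p = 0.90, n = 3). The list as a whole rose in the test with a preset correlation between genes (camera in limma, adjusted p = 3.9e-06), but not with an estimated one (adjusted p = 0.56 with an estimated correlation). Here and below, the estimated variant has little power with 3 arrays, so its missing calls do not show that a shift is absent. Medians of the monocyte and T cell markers, at -0.56 and -0.42, lay on the other side of 0.

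Of the lists of markers of other blood cells, those of T cells, monocytes and cytotoxic cells were called lower in IgMhigh cells. Of 18 tested T cell markers 4 fell and 0 rose (12 and 0 adjusted over the list alone), with a median of -0.42. Besides LCK they included CD3G, a chain of the T cell receptor complex (-0.52 ± 0.12), and CD8A, the co-receptor of cytotoxic T cells (-0.74 ± 0.23). CD3E, another chain of that complex, had a ratio of -1.57 ± 0.71 and missed the threshold (limma adjusted p = 0.051, n = 3). The other probe of CD3E gave -0.64. Of 25 monocyte and macrophage markers 0 passed over all genes and 16, all lower, passed when adjusted over the list alone, with a median of -0.56. The medians of this list were -1.20, -0.50 and -0.19 in animals 651, 827 and 384. CD14, the monocyte receptor for lipopolysaccharide, stood at -2.20 ± 1.51 (limma adjusted p = 0.093, n = 3), and C1QB, a chain of complement C1q, at -0.30 ± 0.15. The 3 probes of CD14 ranged from -2.20 to -0.25. LGALS3, which encodes galectin-3, stood at -0.32 ± 0.10, or 0.30 with median centring in place of loess. Of 16 markers of NK and cytotoxic cells 1 fell (7 adjusted over the list alone), GNLY, a lytic granule protein, while NKG7, another granule protein, stood at -0.37 ± 0.20. GNLY was not well above background in IgMhigh cells on any array. Its mean over the animals was thus at least 1.53-fold higher in IgMlow cells (limma adjusted p = 0.025). This bound sets each dim signal no lower than the lowest one well above background and is open to dye bias. C1QA, another chain of C1q, likewise had a mean at least 2.01-fold higher in IgMlow cells. It missed the threshold (limma adjusted p = 0.069) and stood at -0.51 in animal 384. The T cell, monocyte and cytotoxic lists each fell with the preset correlation (camera adjusted p = 1.7e-06, 2.1e-07 and 3e-05) and were not called otherwise (adjusted p = 0.56 with an estimated correlation for each). Gamma-delta T cell markers (1 of 5 fell, median 0.01), dendritic cell markers (1 of 10 fell, 0.03), neutrophil and eosinophil markers (0 of 11 passed, -0.04) and platelet and erythrocyte markers (0 of 11 passed, 0.04) were not called as lists (camera adjusted p = 0.36, 0.55, 0.21 and 0.99). In Agilent's processed signals the T cell, monocyte and cytotoxic medians were -1.15, -1.12 and -0.48, and the monocyte median was -0.31 without animal 651, -0.84 without animal 384, -0.36 with array quality weights and -0.38 with no filter on dim probes. The T cell median was -0.26 with no filter and also with the filter on both channels and all arrays, and -0.71 with a normexp offset of 16.

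**Figure D3:**
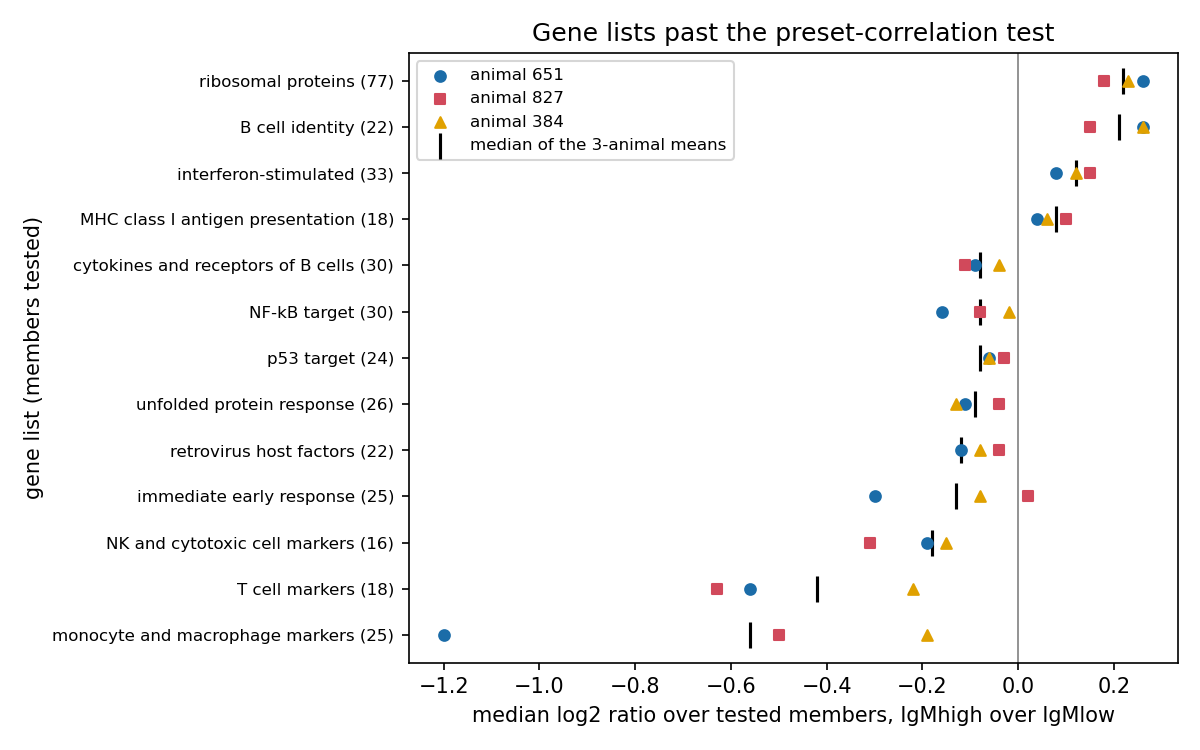
Median log2 ratio of IgMhigh over IgMlow for the 13 gene lists past the test with a preset correlation, per animal (symbols) and for the mean of the animals (black bars), with the number of members tested in brackets. For the mean of the animals, monocyte and macrophage markers lie lowest, and they differ most between animals, from -1.20 to -0.19, while ribosomal protein genes lie between 0.18 and 0.26.

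Inflammatory genes moved in both directions. Of 30 tested NF-kB targets 5 fell and 2 rose (9 and 5 adjusted over the list alone), with a median of -0.08. The chemokines CCL4, CCL3 and CCL5, which attract monocytes and T cells, stood at -1.50 ± 0.29, -0.74 ± 0.16 and -0.60 ± 0.14, and IRF1, a transcription factor induced by interferon, rose by 0.38 ± 0.04, or stood at 0.22 and missed the threshold with the mean of its probes. Among 25 immediate early genes KLF6, a zinc finger transcription factor, fell (-0.63 ± 0.07) and no other passed (1 rose and 4 fell adjusted over the list alone), JUND, a subunit of AP-1, standing at 0.23 ± 0.07. Among 30 cytokines and cytokine receptors of B cells IL2RA, the alpha chain of the interleukin-2 receptor, fell (-0.69 ± 0.18; 0 rose and 2 fell adjusted over the list alone), and IL15, a growth factor of lymphocytes, stood at -0.23 ± 0.05. These lists fell with the preset correlation (camera adjusted p = 0.012, 0.0076 and 0.011), but not otherwise (adjusted p = 0.56 with an estimated correlation for each). With median centring in place of loess the medians were 0.23 for NF-kB targets, 0.34 for immediate early genes and 0.11 for cytokines and receptors, while KLF6 (-0.13), CCL5 (-0.08) and IL2RA (-0.27) missed the threshold. The calls of the NF-kB and immediate early lists were lost without animal 651 (medians -0.07 and -0.05). In the same ratios the monocyte marker median was -0.56 and the T cell marker median -0.42.

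The lists of ribosomal protein, interferon-stimulated and MHC class I presentation genes had small positive medians after loess. With median centring in place of loess, where the median of all genes was 0.26, their medians were 1.11, 0.58 and 0.76. All 77 ribosomal protein genes were tested, and 24 rose and 0 fell (54 and 0 adjusted over the list alone), with a median of 0.22. RPS10, RPS28 and RPL29, components of the small and large ribosomal subunits, rose by 0.65 ± 0.03, 0.57 ± 0.07 and 0.50 ± 0.04. In Agilent's processed signals they stood at 0.48, 0.41 and 0.33 and none passed, and with the mean of a gene's probes RPS10 stood at 0.36 and RPL29 at 0.24, where RPL29 missed the threshold. The median was 0.13 with the mean of a gene's probes and 0.07 in the series table, and in Agilent's processed signals it was 0.08 and the list was not called. Of 33 interferon-stimulated genes 4 rose and 0 fell (10 and 0 adjusted over the list alone), with a median of 0.12. Besides RIGI these were MX1, an antiviral GTPase (0.39 ± 0.04), CXCL10, a chemokine for activated T cells (0.51 ± 0.11), and GBP4, a guanylate-binding protein (0.32 ± 0.04). Of 18 genes of MHC class I presentation BOLA, a class I heavy chain, rose by 0.38 ± 0.06 and no other passed (2 rose adjusted over the list alone), TAP2, a peptide transporter, standing at 0.26 ± 0.03, and the list had a median of 0.08. BOLA stood at 0.16 in Agilent's processed signals, at 0.15 in the series table and at 0.09 with the mean of its probes, and passed in none of these. These lists rose with the preset correlation (camera adjusted p = 1.2e-20, 0.00057 and 0.027), but not otherwise (adjusted p = 0.56 with an estimated correlation for each). The MHC class I list was not called without animal 827 (median 0.05), in Agilent's processed signals (0.06), in the series table (0.05) or with the mean of a gene's probes (0.06), and neither it nor the interferon list was called without the pairing. Monocyte and T cell markers had medians of -0.56 and -0.42 beside these lists.

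The unfolded protein response, p53 target and retrovirus host factor lists had small negative medians, with few genes past the test. Of 26 genes of the unfolded protein response 2 fell and 0 rose (7 and 2 adjusted over the list alone), with a median of -0.09, and these were SESN2, a stress-induced inhibitor of mTORC1 (-0.57 ± 0.11), and TRIB3, a pseudokinase induced by ATF4 (-0.43 ± 0.07). Of 24 p53 targets SESN2 fell and no other passed (1 fell adjusted over the list alone), GADD45A, a DNA damage response gene, standing at -0.70 ± 0.40. Among 22 host factors of retroviruses APOBEC3Z2, a cytidine deaminase of antiviral defence, fell (-0.28 ± 0.03; 1 rose and 2 fell adjusted over the list alone), and PSIP1, which tethers lentiviral integrase to chromatin, stood at -0.31 ± 0.09. These lists fell with the preset correlation (camera adjusted p = 0.012, 0.012 and 0.023), but not otherwise (adjusted p = 0.56 with an estimated correlation for each), and with median centring in place of loess their medians were 0.36, 0.28 and 0.34, where the unfolded protein response list was called higher (camera adjusted p = 0.02) and the others were not called. The unfolded protein response list was not called without animal 384 (-0.09), the retrovirus list not without animal 651 (-0.06), and neither without the pairing. Of 18 heat shock genes 0 passed, with a median of -0.02, and the list was not called (camera adjusted p = 0.22). SESN2, TRIB3, APOBEC3Z2 and PSIP1 stood at 0.00, 0.16, 0.28 and 0.14 with median centring. The monocyte and T cell marker medians of -0.56 and -0.42 accompanied these shifts as well.

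Genes of B cell fate and regulation fixed for naming beforehand mostly stayed within the spread between animals. PRDM1 and XBP1, transcription factors of plasma cells, stood at 0.00 ± 0.22 and -0.21 ± 0.10, and BCL6, the regulator of germinal centre B cells, at -0.28 ± 0.40. CD5, a marker of B-1 cells, and CD27, a memory marker, stood at 0.05 ± 0.09 and -0.03 ± 0.08. The cytokines IL10 and TGFB1, both immunosuppressive, stood at -0.34 ± 0.35 and 0.11 ± 0.08, MYC, a driver of growth, at -0.32 ± 0.18, BCL2, which blocks apoptosis, at 0.07 ± 0.09 and FAS, a death receptor, at -0.14 ± 0.21. None of these 10 genes passed in limma, with adjusted p-values from 0.090 for MYC to 0.98 for PRDM1. CD274, PDCD1LG2 and MKI67 had 0 probes named for them.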

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

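All alternatives here were planned. The number of genes past the threshold (475, with 262 higher and 213 lower) moved by over 1.5 times under most of them, and the cause was not tested unless named. It was 233 (97 and 136) without background correction, 65 (20 and 45) with a normexp offset of 16, 23 (3 and 20) with Agilent's processed signals, 45 (17 and 28) with the series table, 776 (418 and 358) with scale normalization between arrays and 12129 (10124 and 2005) with median centring and no loess. The share of higher genes, 55.2% at first, was 41.6%, 30.8%, 13.0%, 37.8%, 53.9% and 83.5% in that order. It was 285 (146 and 139) with no filter, where more genes were tested, 736 (424 higher) with the filter on both channels and all arrays, 183 (77 and 106) with the mean of a gene's probes, 1108 (653 and 455) with an intensity trend and robust prior and 910 (531 and 379) with array quality weights. Those weights were 0.75, 0.77 and 1.73 for animals 651, 827 and 384. With no replicate block it was 1 (0 higher and 1 lower), since differences between animals then entered the error, while 9 of the 13 list calls remained. At least 2-fold change left 49 genes, and an adjusted p under 0.1 gave 2013. Leaving out an animal gave 0 to 224 genes (0 to 36 higher, 0 to 188 lower), with fewer samples in each fit.

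The count of 2-fold genes of one sign (120) was 535 with processed signals and 233 with median centring, and 93 to 167 without an animal. The 13 list calls fell to 0 with an estimated correlation, and were 10 to 16 without an animal. IGHM (0.05) was 0.74 and past the threshold with median centring, and -0.01 to 0.11 without an animal, turning below 0 without animal 384.

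Median centring without loess moved genes by a median of 0.28, and the median of all genes was 0.26. On that scale these changed sign: JCHAIN (0.14), CD79B (0.41), PRDM1 (0.40), XBP1 (0.33), BCL6 (0.14), MYC (0.35), FAS (0.23), LGALS3 (0.30), SESN2 (0.00), TRIB3 (0.16), APOBEC3Z2 (0.28), PSIP1 (0.14), ANXA2 (0.11), LYZ (0.41), CD3D (0.22), and the lists of immediate early (0.34), unfolded protein response (0.36, called higher), p53 target (0.28), retrovirus host factor (0.34), DNA replication (0.33), NF-kB target (0.23) and cytokine and receptor genes (0.11). Other changes of sign were of ratios near 0: CD79B (0.02) and CD27 (0.01) with processed signals, CD79B (0.01) with the series table, CD5 (-0.02) with the mean of probes, and PRDM1 with scale normalization (0.01) and array weights (0.07). Without an animal the ratio was -0.07 to 0.06 for CD79B, -0.01 to 0.08 for CD5, -0.13 to 0.07 for PRDM1 and -0.21 to 0.11 for LYZ. Of 56 named genes past the threshold 0 stayed past it under every alternative, and of 13 lists 0 kept the call with an estimated correlation, while 4 kept it under every change to values, filter or fit. Signal over background limits the dimmest genes: 15 genes past the threshold were not well above background in IgMhigh cells on any array, and 5 in IgMlow cells.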

Other observations

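Some genes of lists that were not called passed the test singly. Among 32 tested oncogenes and lymphoma-associated genes CDK6, a kinase of cell cycle entry, fell (-0.34 ± 0.03, SD, n = 3). That list had camera adjusted p = 0.052. Among 23 trafficking genes CD44, a receptor for hyaluronan, fell (-0.53 ± 0.07). CXCR6, a receptor of effector T cells, was not well above background in IgMhigh cells. Its mean was at least 2.69-fold higher in IgMlow cells (limma adjusted p = 0.047), with a ratio of -0.84 in animal 384. Among 17 tested inhibitory receptors and ligands PDCD1, which encodes PD-1, fell (-0.43 ± 0.12). PRKCB, the protein kinase C of B cell receptor signalling, rose (0.35 ± 0.04), as did BOLA-DOB, a modulator of MHC class II loading (0.36 ± 0.08). ANXA2, an annexin in the memory B cell list, and TSC22D3, a glucocorticoid-induced gene in the naive B cell list, both fell (-0.38 ± 0.07 and -0.45 ± 0.07), ANXA2 standing at 0.11 with median centring. Among 28 genes of mitosis UBE2C, which targets cyclins for degradation, and CENPF, a kinetochore protein, fell (-0.32 ± 0.04 and -0.28 ± 0.04), and among 36 of DNA replication MCM10, a replication initiation factor, fell (-0.36 ± 0.08) while CCNE1, cyclin E1, stood at 0.36 ± 0.13.

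Beyond CCL2 and CXCL8, further chemokines had large negative ratios that missed the threshold, and they were picked after their values were seen. CXCL5, CXCL2 and CXCL3, which attract neutrophils, stood at -3.78 ± 1.90, -3.40 ± 1.72 and -3.24 ± 1.61, and THBS1, a matrix protein of monocytes and platelets, at -3.93 ± 1.99 (limma adjusted p = 0.057 to 0.058, n = 3). Each was most unequal in animal 651 and least in animal 384, where THBS1 stood at -5.86 and -1.89. The median of the monocyte and macrophage markers was -1.20 in animal 651, -0.50 in animal 827 and -0.19 in animal 384. The SD of the ratios over all tested genes had the same order (0.30, 0.25 and 0.17). The medians of T cell markers (-0.56, -0.63 and -0.22) and of B cell identity genes (0.26, 0.15 and 0.26) did not. The order was thus not shared by all sets of genes, and its cause was not tested.

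Among the tests that follow, those on RNA without a poly(A) tail, S phase, GC content and probe-specific dye bias, and for ribosomal genes the use of processed signals and of the nearest genes in intensity, were chosen after the results were seen, and the histone set was defined after histone ratios were seen. The first pattern is the lower ratio of monocyte and T cell markers. A dye effect on dim probes is argued against, since at a percentile of 0 both medians lay below all of 10000 random lists matched on intensity, and so is GC content, whose trend spanned 0.03 over all genes. RNA of other cell types in the IgMlow sort may account for it, although any gate on B cells should remove such cells. At least 72.2% of each list, against 22.6% of all genes, was negative in all 3 animals. That share restates the pattern itself. A true difference in B cell transcripts or a dye bias of the single probes could give it too, so it does not decide between them. Several bright members lay on the positive side of their list's median, with LYZ at -0.09 ± 0.35, CD3D at -0.25 ± 0.34 and CD4 at 0.12 ± 0.11. LGALS3 (-0.32 ± 0.10) and CTSD (-0.23 ± 0.15) did so too, but were negative in all 3 animals. TYROBP stood at the median of its list (-0.56 ± 0.92), and S100A8, a dimmer marker, at -2.13 ± 1.61. All but LGALS3 were picked after their values were seen. In IgMhigh cells 18 of 25 monocyte and 14 of 18 T cell markers were well above background on all arrays, 3 markers stood in another list too, and a true difference in B cell transcripts stays open.

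The second pattern is the excess of ribosomal protein genes in IgMhigh cells. An intensity-dependent dye effect is argued against as the whole cause, since the median of 0.22 lay at a percentile of 100 among 10000 random lists of other genes nearest in intensity (95% of them between 0.00 and 0.15), and so did the 0.08 of Agilent's processed signals (-0.10 to 0.01). Few genes are as bright, so these lists drew on 120 and 117 other genes, with median log2 intensities of 17.24 and 17.20 against 17.19 and 17.23 for the ribosomal genes. The trend on GC content spanned 0.03. A dye bias of the single probes cannot be told apart from a difference in the cells, because dyes were never swapped and the median varied by 0.08 between arrays, as either would allow. A difference between IgMhigh and IgMlow cells stays open and untested.

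The third pattern, in IgMlow cells, is an excess of histone transcripts and of U1a RNA, whose single probe stood at -2.45 ± 0.32 (SD, n = 3; limma adjusted p = 0.0088) and was picked after its value was seen. Of 54 replication-dependent histone genes and probes 26 fell and 0 rose, with a median of -0.83, and they made up 23 of the 48 decreases of at least 2-fold. Unequal labelling of RNA without a poly(A) tail is a candidate explanation, since 8 replacement histones that carry a tail had a median of 0.02, but TERC, also without a tail, stood at 0.02 ± 0.02. More cells in S phase among IgMlow cells stays open, as the DNA replication list had a median of -0.04 in genes bright enough to hide a small share of cells. Genomic DNA in the IgMlow reaction stays open too: olfactory receptor probes lay at percentile 94.4 of matched random lists, but they lie near the floor of the arrays and exclude nothing.

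Turning the sign of 1 array at a time, 1 of the 4 orientations, the real one, gave as many as 475 genes, and the highest of the others gave 0. With 4 orientations no share under 0.25 can be had, too few for a test of chance.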
